A study of Mus musculus with 15 samples.

How the data were processed

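Total RNA from snap-frozen normal choroid plexus and from its papillomas and carcinomas in mice was profiled on 15 single-channel Affymetrix GeneChip arrays with 1 biotin-labelled sample each. The groups were taken from the sample titles, with 5 arrays per group, and the series description gives the samples of a group as tissue from different animals. The deposited values are on a log2 scale and are RMA summaries per probe set, per the submitters' processing notes, which name RMA and Affymetrix Expression Console without a version. RMA subtracts background, forces the arrays to a shared intensity distribution and summarises the probes of a set on the log2 scale, so small changes of dim probe sets are compressed and a global change in RNA content is removed. The genome build behind the probe annotation is not given in the sources used here. The median of the deposited log2 values was 6.79 to 6.90 per array and the highest value 14.48 to 14.58. Arrays have no read depth, and the number of arrays limits the precision of each value.

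The table held 41345 probe sets, of which 190 were controls. A pairing table gave exactly 1 gene symbol to 23521 probe sets, several to 1814 and none to 16010. Of the 23521, 23328 matched a gene of the mouse RefSeq gene table (assembly GRCm38.p6) through the Entrez identifier. That table was used for names, for the chromosome of each gene and, through its start position, for the order of genes along the chromosome. Positions were used for this order alone. Where a gene had more than 1 probe set, as 1082 genes did, the set with the highest mean over the 15 arrays stood for the gene, which left 22180 genes to test. Probe sets with several symbols or none entered only the alternative on all probe sets. Trp53, the gene of p53, was not analysed here because no probe set was paired with it alone.

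Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with the group as its only term was fitted to all 15 arrays, which left 12 residual degrees of freedom, and eBayes moderated the variances without a trend (3.35 prior degrees of freedom). The comparisons were carcinoma minus normal, papilloma minus normal and carcinoma minus papilloma. The p-values are two-sided and adjusted by Benjamini-Hochberg over the 22180 genes, with a threshold of 0.05. A gene was also counted as changed at least 2-fold where its log2 change was 1 or more in size. Gene values are given as the mean log2 value ± SD with n = 5 per group, and changes as log2 differences with their standard error (SE). Fold values are 2 raised to the size of the log2 difference. The replicate numbers in the titles were not used as a block, because arrays of the same number did not deviate together. Tests on single values with 5 against 5 were exact permutation tests over 252 splits, whose smallest two-sided p is 0.00794.

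The 35 gene lists (890 entries, of which 797 were measured) were written before the data were examined, as were the comparisons, the threshold, the rule for named genes and the first set of alternatives. Which lists the text describes for each comparison was chosen after seeing the data. The 32 lists with at least 5 measured genes were tested by limma's camera with a preset correlation of 0.01, adjusted over the lists. Camera asks whether a list moved more than the other genes did, and its preset correlation is low for genes that vary together between tumours. Each camera p is therefore given with the p obtained when the correlation was estimated from the data. Calls that held with an estimated correlation numbered 2 of 19 lists for carcinoma against normal, 4 of 16 for papilloma against normal and 3 of 16 for carcinoma against papilloma. Limma's fry tests whether a list's genes move one way on balance, and its mixed p whether they change in either direction. Neither compares the list with other genes. Genes were named by a fixed rule. It took per comparison the 8 largest rises and 8 largest falls among genes past the threshold with no overlap between the arrays of the groups, leaving out predicted genes, clone names, microRNAs, small nucleolar RNAs, olfactory and vomeronasal receptors and immunoglobulin segments. It also took Myc and Atoh1, and of each list described up to 3 members past the threshold with the largest change in the main direction and 1 in the other, or, where no member passed, up to 2 values with the smallest p. Genes named outside this rule are said to be so.

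The alternatives chosen before the data were examined were a replicate block, a variance trend with robust moderation, array quality weights, a fit on only the groups compared, quantile normalization over all probe sets, a common median, a filter that kept genes above the median of all probe sets in at least 5 arrays, all probe sets, the mean of a gene's probe sets, an unpooled variance per gene and group, and leaving out each array. After seeing the data, 4 more were added: carcinoma arrays with each autosome's median shift removed, no genes on X and Y, 1 array weight per group, and papilloma arrays 2 and 4 left out. Chromosome-wide shifts were computed from the 13738 autosomal genes that were above the median of all probe sets in at least 5 arrays. Each gene's difference from the mean of the normal arrays (of the other normal arrays for a normal array) was taken, the median over all these genes was subtracted per array, and the median per autosome was kept. Overlap between the comparisons that share the normal arrays was set beside 20 simulated data sets without any group difference. It was also set beside splits of the normal arrays into groups of 2 and 3. The 10 possible splits were each used both ways, which gave 20 overlaps.

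The steps were tested on simulated data with known changes among the 22180 genes. For carcinoma against normal, 54.3% of genes changed by a log2 value of 0.5 were recovered, 94.1% at 1 and 96.8% at 2. For papilloma against normal the shares were 48.4%, 91.7% and 96.9%, and for carcinoma against papilloma 61.9%, 84.3% and 98.8%. At most 0.296% of unchanged genes were called. In each simulated comparison 21980 of the 22180 genes were unchanged, whereas far more genes passed the threshold in the real comparisons. The adjustment is less strict where more genes change, so these shares need not hold for the real comparisons. All 20 of the simulated lists shifted by 0.5 were called in carcinoma against normal and 0 of 180 unshifted lists. The simulated genes varied independently of each other, so this does not give the rate of false calls for lists whose genes vary together. The estimated correlation of the real lists reached 0.722, in the mitotic list. A simulated chromosome shift of -0.3 was recovered as -0.289. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.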

Results

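Expression was measured in 15 mouse tissues: 5 samples of normal choroid plexus, 5 choroid plexus papillomas and 5 choroid plexus carcinomas. The choroid plexus is the secretory tissue of the brain ventricles that makes cerebrospinal fluid, and papilloma and carcinoma are the benign and malignant tumours of its epithelium. Per the labels, papillomas came from mice with Atoh1-Cre and Myc alleles, carcinomas from mice that also carried floxed p53, and normal tissue from mice with the Myc and floxed p53 alleles and no Cre. The comparisons therefore set each tumour type against normal tissue and the tumour types against each other. The first principal component of the 15 arrays held 53.9% of the variance and separated normal tissue (-60.41 to -57.91) from tumours (17.53 to 45.55). The second held 13.6% and separated carcinomas (14.62 to 31.21) from papillomas (-31.48 to -24.34). The median SD over genes was 0.12 in normal tissue, 0.15 in papilloma and 0.19 in carcinoma.

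Myc, the transcription factor whose alleles the labels name (probe set 17311846, chromosome 15), measured 7.65 ± 0.09 in normal tissue, 8.26 ± 0.17 in papilloma and 8.46 ± 0.34 in carcinoma (mean log2 ± SD, n = 5 each). It rose by 0.80 (SE 0.14, limma adjusted p = 0.000166) in carcinoma and by 0.60 (SE 0.14, adjusted p = 0.00228) in papilloma, with every tumour array above every normal array. The tumour types differed by 0.20 (SE 0.14, adjusted p = 0.404). Atoh1, whose regulatory sequence drives Cre, measured 6.76 ± 0.11, 6.87 ± 0.11 and 6.73 ± 0.21 in the same order, close to the median of all probe sets, and no comparison passed the threshold (adjusted p = 0.473, 0.845 and 0.428 for papilloma against normal, carcinoma against normal and carcinoma against papilloma). These probe sets do not tell a floxed or added allele from the normal one, so they check the labels only in part. Sex-linked transcripts gave a further check. Each of the 10 tumour arrays had either Xist, the X-inactivation transcript of female cells, or the Y-linked Uty, Eif2s3y and Kdm5d. Normal arrays 2 to 5 had both, with Xist at 10.69 to 12.48 and the Y-linked mean at 7.72 to 9.74.

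**Figure D1:**
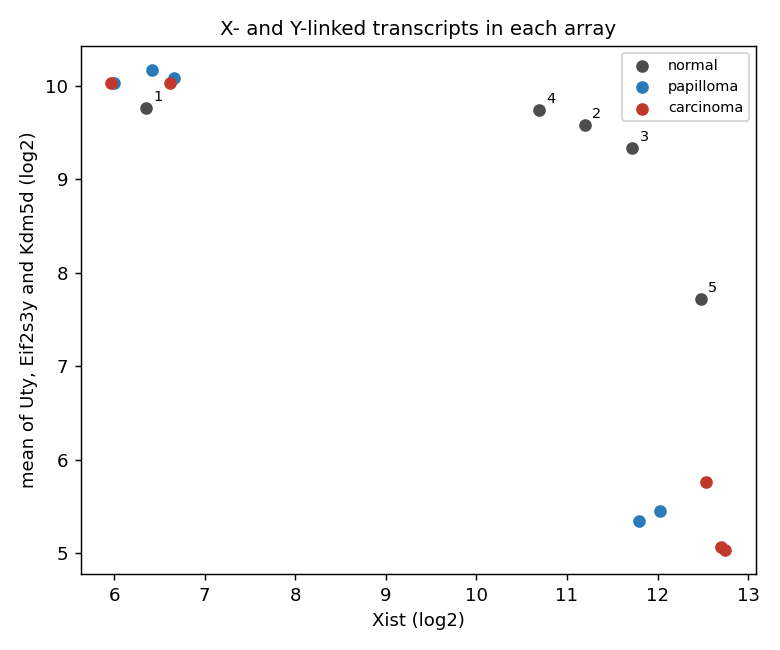
Log2 value of Xist (horizontal axis) against the mean log2 value of the Y-linked genes Uty, Eif2s3y and Kdm5d (vertical axis), 1 point per array, coloured by group, with the replicate number beside normal arrays. Tumour arrays lie at the upper left (Xist at most 6.66) or the lower right (Y-linked mean at most 5.76), and normal arrays 2 to 5 lie between.

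Carcinomas differed from normal choroid plexus by a gain of cell division and growth transcripts and a loss of multiciliated cell transcripts. With an estimated correlation the ribosome biogenesis call held (adjusted p = 0.00801), and the mitotic and multiciliated calls were lost (adjusted p = 0.0999 and 0.0757). All 39 measured mitotic genes rose, led by Ccnb2, a mitotic cyclin (up 4.54, SE 0.18, adjusted p = 4.56e-11, 23.2-fold), Cks2 (up 4.04) and the proliferation marker Mki67, which went from 6.83 ± 0.14 to 10.80 ± 0.54 (n = 5 each). Ribosome biogenesis genes rose in 44 of 46 cases. The multiciliated cell genes fell in 36 of 45 cases, among them the radial spoke gene Rsph4a (fell by 4.51 on the log2 scale, adjusted p = 2.3e-09). In all, 8403 of 22180 genes passed the threshold, 4151 higher and 4252 lower in carcinoma, and 979 and 988 of these changed at least 2-fold. The arrays of the groups did not overlap in 29.9% of genes, against 0.794% by chance.

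The 8 largest rises were Egln3, an oxygen-sensing prolyl hydroxylase (up 5.01, SE 0.37, 32.3-fold, adjusted p = 3.34e-08), Esco2, a cohesin acetyltransferase (up 4.80), Mab21l1 (up 4.72), Gpnmb, a glycoprotein also made by macrophages (up 4.70), Ccnb2, the BMP antagonist Chrdl1 (up 4.29), the replication regulator Dtl (up 4.28) and the mitotic kinase Pbk (up 4.12). The 8 largest falls were Tmprss11a, a serine protease (fell by 5.60 on the log2 scale, SE 0.17, 48.4-fold, adjusted p = 7.03e-12), Slc7a10, an amino acid transporter (-4.71), Cdkl4 (-4.70), Rsph4a, Vwa3a (-4.47), the cilia gene Drc7 (-4.34), the cilia-associated adenylate kinase Ak7 (-4.24) and the methyltransferase Inmt (-4.15). Tmprss11a was at 4.94 to 5.84 in the carcinomas, below the median of every array. Folds and ranks of falls that end so low are uncertain.

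Among the lists, the mitotic genes had a median log2 change of 2.61 (39 higher and 0 lower, also when adjusted over the list alone; camera adjusted p = 2.72e-31, and 0.0999 with an estimated correlation). DNA replication genes rose in 35 of 39 cases and fell in 0 (35 and 0 adjusted over the list alone), with Dtl, the helicase subunit Mcm3 (up 2.88) and the polymerase subunit Pole (up 2.78) ahead (camera adjusted p = 2.34e-21, and 0.0867 with an estimated correlation). The dimmer probe set of Pole differed by only 0.09. Of 27 homologous recombination and Fanconi genes, 20 rose and 1 fell (21 and 1 adjusted over the list alone), with Fanci (up 1.98), Rad54l (up 1.91) and Brca1 (up 1.79) higher and Fancl lower (-0.49) (camera adjusted p = 1.94e-08, and 0.111 with an estimated correlation). Ribosome biogenesis genes had a median of 1.14, with 44 higher and 1 lower (45 and 1 adjusted over the list alone). Polr1b, a subunit of RNA polymerase I, rose by 1.99, Gnl3 by 1.96 and Nop2 by 1.82, and Polr1a fell by 0.50 on the log2 scale. This call held both ways (camera adjusted p = 3.09e-30, and 0.00801 with an estimated correlation). Nucleotide and polyamine synthesis genes also held both ways (18 higher and 1 lower of 22, also when adjusted over the list alone; camera adjusted p = 2e-13, and 0.00517 with an estimated correlation). Their largest rises were the serine hydroxymethyltransferases Shmt1 (up 3.35) and Shmt2 (up 2.28) and the spermidine synthase Srm (up 2.13). The gene that fell was Mthfd1 (-0.38), whose call ended once chromosome-wide shifts were removed, an alternative chosen after seeing the data (-0.19, adjusted p = 0.0643).

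Multiciliated cell genes had a median of -2.02 (4 higher and 36 lower of 45, 5 and 37 adjusted over the list alone; camera adjusted p = 1.86e-16, and 0.0757 with an estimated correlation). The falls were led by Rsph4a, Ak7 and the dynein light chain Dynlrb2 (-3.54), while Deup1, which builds the deuterosomes that multiply centrioles, rose by 3.42 (SE 0.27, adjusted p = 7.52e-08). Choroid plexus epithelial genes fell more modestly, with a median of -0.49 (2 higher and 22 lower of 35, 3 and 24 adjusted over the list alone; camera adjusted p = 9.02e-05, and 0.237 with an estimated correlation). The sulfatase Sulf1 (-2.55), the carbonic anhydrase Car2 (-1.74) and the iodide transporter Slc5a5 (-1.70) fell most, and the transcription factor Lmx1a rose by 0.30. Ttr, the main secretory product of this epithelium and named after its values were seen, measured 14.42 to 14.58 in all 15 arrays. That is at or within 0.10 of the highest value of each array.

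The p53 target genes went both ways (11 higher and 15 lower of 41, 12 and 15 adjusted over the list alone; camera adjusted p = 0.70). Psrc1 rose by 1.78, and the falls were led by Pltp, a lipid transfer protein (4-fold lower, adjusted p = 0.000661), the kinase Plk2 (-1.79) and the polymerase Polk (-1.33). Among G1 regulators 11 of 17 rose and 3 fell (also when adjusted over the list alone), with the CDK inhibitor Cdkn2c (6.04-fold), cyclin Ccnd1 (up 2.06) and Rbl1 (up 2.03) higher and the CDK inhibitor Cdkn1c lower (-1.18) (camera adjusted p = 0.00341, and 0.131 with an estimated correlation). Glycolysis and hypoxia genes rose in 17 of 25 cases and fell in 1 (also when adjusted over the list alone; camera adjusted p = 3.98e-06, and 0.331 with an estimated correlation), led by Egln3, Adm (up 2.84) and Ndrg1 (up 2.35), while Pfkm fell by 0.30 on the log2 scale, a call that ended at a common median (-0.26, adjusted p = 0.0515) and with an unpooled variance per group.

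Endothelial genes rose in 13 of 21 cases and fell in 0 (14 and 0 adjusted over the list alone), among them Esm1 (up 2.39), Plvap (up 1.24) and Robo4 (up 1.10) (camera adjusted p = 3.32e-05, and 0.303 with an estimated correlation). Meningeal genes fell in 10 of 15 cases and rose in 2 (also when adjusted over the list alone), with the transporter Slc47a1 (-2.70), Cdh1 (-1.77) and Ccn3 (-1.74) lower and Crabp2 higher (up 2.10) (camera adjusted p = 3.54e-05, and 0.0757 with an estimated correlation). Mature neuron genes fell in 9 of 20 cases and rose in 0 (0 higher and 11 lower adjusted over the list alone; camera adjusted p = 0.0028, and 0.608 with an estimated correlation). Their mean was 7.86 to 8.34 in the normal arrays and 6.94 to 7.48 in the carcinomas. The synaptic gene Snap25 (-2.53), the neurofilament gene Nefl (-1.78) and the glutamate receptor gene Gria2 (-1.36) were lowest. The call of Snap25 ended without normal array 1, 2 or 5 or carcinoma array 5 (-2.52 to -1.99, adjusted p = 0.0522 to 0.0816). The call of Gria2 ended without normal array 2 or carcinoma array 1 or 5 (-1.32 to -1.26, adjusted p = 0.0505 to 0.0542). Gh, a pituitary hormone gene chosen after its values were seen, was at 9.66 to 10.36 in the normal arrays and 6.52 to 8.17 in the tumours. For the meningeal, neuron and oligodendrocyte lists, a change in either tumour type cannot be told apart from other tissue dissected with the normal samples. The cells that gave the multiciliated and fibroblast transcripts of the normal samples were not identified, so the same limit applies to these lists.

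Oligodendrocyte lineage genes fell in 10 of 15 cases and rose in 1, also when adjusted over the list alone (camera adjusted p = 0.00672, and 0.421 with an estimated correlation). The tight junction gene Cldn11 (-2.40), Ermn (-1.11) and the myelin gene Mag (-1.09) fell most. Cspg4 rose by 0.24, a call that ended without normal array 1, 2 or 4 or carcinoma array 1 (0.17 to 0.23, adjusted p = 0.055 to 0.0773). Immediate early genes rose in 9 of 19 cases and fell in 0 (10 and 0 adjusted over the list alone; camera adjusted p = 0.00341, and 0.571 with an estimated correlation). Ccn1 (up 2.44) and the transcription factor genes Atf3 (4.01-fold) and Jun (up 1.87) led them.

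**Figure D2:**
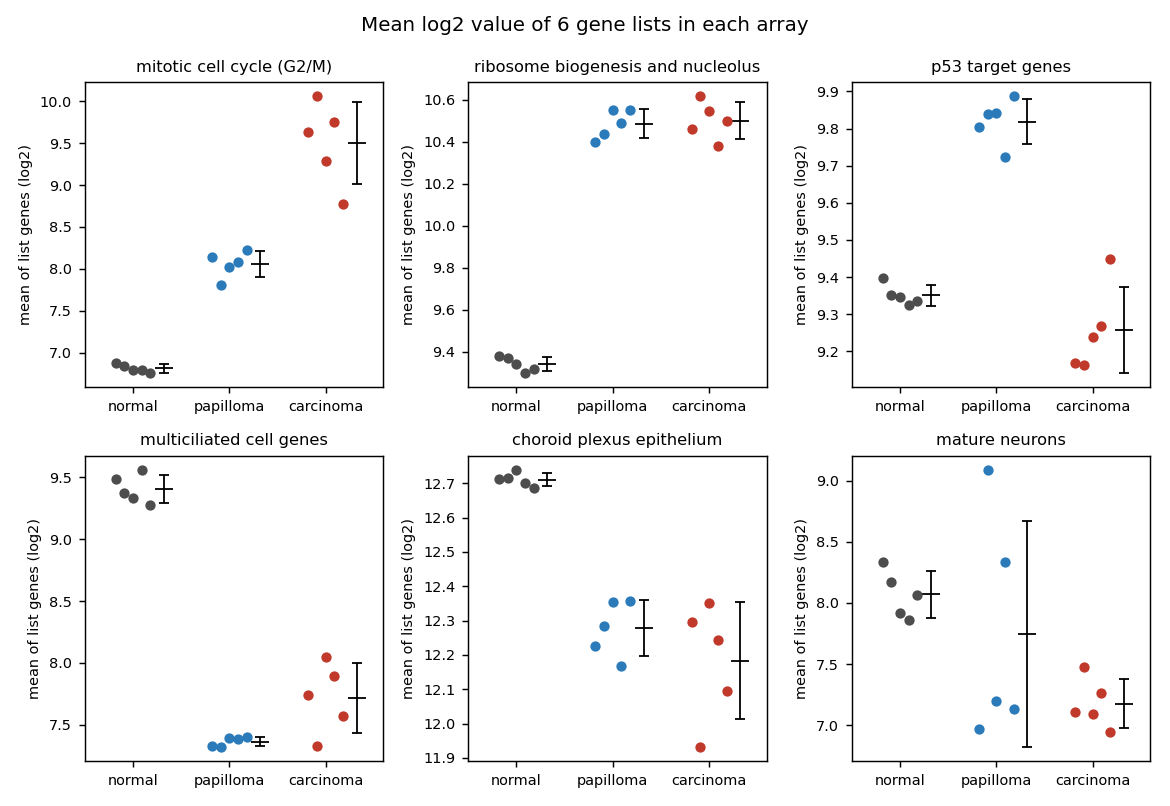
Mean log2 value (vertical axes) of the measured genes of 6 lists in each array, by group, with 1 point per array and the group mean ± SD (n = 5) beside the points; each panel has its own scale. Mitotic genes lie at 6.75 to 6.88 in normal tissue, 7.81 to 8.23 in papilloma and 8.78 to 10.06 in carcinoma, and p53 target genes are highest in papilloma (9.72 to 9.89).

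Papillomas shared the gain of growth transcripts and the loss of multiciliated cell transcripts with a smaller rise of mitotic genes, and of 41 p53 target genes 20 rose and 5 fell. With an estimated correlation the calls of the ribosome and multiciliated lists held (adjusted p = 0.00616 and 0.0223), and those of the mitotic and p53 target lists were lost (adjusted p = 0.329 and 0.111). Ribosome biogenesis genes were higher in 44 of 46 cases, with a median of 1.14. Multiciliated cell genes fell in 36 of 45 cases, with Rsph4a down from 11.56 ± 0.13 to 6.33 ± 0.21 (n = 5 each). The CDK inhibitor and p53 target Cdkn1a rose by 2.07 (SE 0.21, adjusted p = 1.03e-06, 4.19-fold), to 12.73 ± 0.06. In all, 7374 genes passed the threshold, 3763 higher and 3611 lower in papilloma, and 764 and 888 of these changed at least 2-fold. The groups did not overlap in 32.1% of genes, against 0.794% by chance.

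The 8 largest rises were Egln3 (up 4.59, SE 0.37, adjusted p = 9.81e-08), Chrdl1 (up 4.40), the sialyltransferase St8sia6 (up 4.31), Psrc1 (up 3.97), the fatty acid binding protein Fabp4 (up 3.95), Gxylt2 (up 3.90), the vesicular glutamate transporter Slc17a8 (up 3.73) and Erc2 (up 3.73). The 8 largest falls were Tmprss11a (fell by 5.39 on the log2 scale, SE 0.17, 42.0-fold, adjusted p = 6.93e-12), Iqub (-5.39), Rsph4a (-5.23), Drc7 (-5.05), the chemokine Ccl9 (-4.84), Stk32a (-4.68), the cilia gene Cfap52 (-4.52) and Cdkl4 (-4.48). In the papillomas Tmprss11a was at 5.25 to 6.08 and Rsph4a at 6.06 to 6.61, below the median of every array. The fold and rank of such falls are uncertain.

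Mitotic genes had a median of 1.11 (36 higher and 1 lower of 39, 37 and 1 adjusted over the list alone; camera adjusted p = 1.22e-14, and 0.329 with an estimated correlation). Ccnb2 rose by 3.08, Cks2 by 2.82 and Mki67 by 2.29. The lower gene was the separase Espl1 (-0.32, adjusted p = 0.0446), whose call ended without normal array 1, 2, 4 or 5 or any 1 papilloma array (-0.34 to -0.29, adjusted p = 0.0508 to 0.0943) under quantile normalization or a common median (-0.27 in both), and on all probe sets (adjusted p = 0.0629). It also ended without papilloma arrays 2 and 4, an alternative chosen after seeing the data (adjusted p = 0.157). Ribosome biogenesis genes (44 higher and 1 lower of 46, also when adjusted over the list alone) were led by Polr1b (up 1.98), Rcl1 (up 1.87) and Nob1 (up 1.78), and Polr1a fell by 0.52 on the log2 scale (camera adjusted p = 6.56e-32, and 0.00616 with an estimated correlation). Nucleotide and polyamine synthesis genes rose in 19 of 22 cases and fell in 0, also when adjusted over the list alone, with Shmt1 (up 2.89), Srm (up 2.03) and Shmt2 (up 1.89) ahead (camera adjusted p = 3.04e-14, and 0.00381 with an estimated correlation).

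Among p53 target genes 20 of 41 rose and 5 fell (23 and 6 adjusted over the list alone; camera adjusted p = 0.000354, and 0.111 with an estimated correlation). Psrc1, the receptor Eda2r (up 3.39) and Cdkn1a rose most, and Pltp fell by 4.17 on the log2 scale. Among G1 regulators 7 of 17 rose and 2 fell, also when adjusted over the list alone, with Cdkn1a, Cdkn2c (up 1.76) and cyclin Ccne1 (up 1.42) higher and Cdkn1c lower (-2.81, SE 0.09, adjusted p = 8.16e-12). The camera call of this list (adjusted p = 0.031) was lost with an estimated correlation (adjusted p = 0.329), under quantile normalization (adjusted p = 0.0591) and with dim genes left out (adjusted p = 0.0526).

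Multiciliated cell genes had a median of -2.36 (3 higher and 36 lower of 45, 4 and 38 adjusted over the list alone; camera adjusted p = 4.12e-24, and 0.0223 with an estimated correlation). Rsph4a, Cfap52 and Ak7 (-4.31) fell most, and Deup1 rose by 2.13. Choroid plexus epithelial genes had a median of -0.35 (1 higher and 16 lower of 35, 2 and 17 adjusted over the list alone; camera adjusted p = 0.000495, and 0.329 with an estimated correlation). The peptidase Ace (-2.33), Car2 (-2.12) and Rdh5 (-1.48) fell most, and the transporter Slc29a4 rose by 0.63. Meningeal genes fell in 11 of 15 cases and rose in 0, also when adjusted over the list alone, with Slc47a1 (-2.54), Ccn3 (-1.79) and Cdh1 (-1.78) lowest (camera adjusted p = 4.31e-08, and 0.0223 with an estimated correlation). Fibroblast, pericyte and matrix genes went both ways (9 higher and 14 lower of 28, 9 and 15 adjusted over the list alone; camera adjusted p = 0.107), with the proteoglycans Lum (-3.37) and Dcn (-3.14) and the fibronectin gene Fn1 (-1.99) lower and the smooth muscle actin gene Acta2 higher (up 2.62). Wnt and BMP pathway genes fell in 13 of 29 cases and rose in 5 (5 higher and 14 lower adjusted over the list alone; camera adjusted p = 0.031, and 0.111 with an estimated correlation, and 0.0526 with dim genes left out). The ligand genes Bmp6 (-2.53), Bmp5 (-1.58) and Rspo3 (-1.38) were lower, and Dkk3 was higher (up 3.15).

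Mature neuron genes did not move as a list (0 higher and 3 lower of 20, also when adjusted over the list alone; camera adjusted p = 0.179), with Nefl (-1.29), Slc17a6 (-0.71) and Nefm (-0.68) lower. Their mean was 9.09 in papilloma array 2 and 8.34 in papilloma array 4, against 6.97 to 7.20 in the other papillomas. Astrocyte genes were likewise at 9.43 and 8.84 in arrays 2 and 4 against 8.20 to 8.29. The neuron list passed the threshold as lower without papilloma array 2 (camera adjusted p = 0.00172) and without arrays 2 and 4 (9.53e-08), the latter chosen after seeing the data.

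The changes of both tumour types against normal tissue overlapped. Of the genes past the threshold, 2911 were higher in both and 2863 lower in both, and 54 went in opposite directions (31 higher in carcinoma and lower in papilloma, 23 the reverse). Egln3 and Chrdl1 were among the 8 largest rises of both, and Tmprss11a, Cdkl4, Rsph4a and Drc7 among the 8 largest falls of both. Independent lists of the same lengths would share 704 and 692 genes. Simulated groups without any change, set against simulated normal arrays that they had in common, shared at most 1 and 2. They had at most 10 calls in any direction, so their shared counts could not be large. Those counts do not measure how far common controls raise the overlap. With different normal arrays for each tumour type the medians were 1982 and 1868 shared genes over 10 splits, each used both ways. Across genes, which are not independent replicates, the log2 changes had a covariance of 0.319 against 0.0062 from shared controls alone, and 0.313 with split controls. Changes of at least 2-fold in both were shared by 558 higher and 680 lower genes, with 2 in opposite directions.

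Carcinomas differed from papillomas, the comparison in which the tumour genotypes differ by floxed p53, by higher cell division transcripts and lower p53 target genes. With an estimated correlation the p53 target call held (adjusted p = 0.00727) and the mitotic call was lost (adjusted p = 0.0549). Mitotic genes were higher in 38 of 39 cases, with Bub1, a spindle checkpoint kinase, up by 2.04 (SE 0.27, adjusted p = 0.000191, 4.10-fold). Of 41 p53 target genes 20 were lower and 1 higher, with Cdkn1a at 9.86 ± 0.59 in carcinoma and 12.73 ± 0.06 in papilloma (-2.87, SE 0.21, adjusted p = 1.46e-06; n = 5 each). The calls of Cdkn1a and Bub1 ended when each gene's variance was taken per group without pooling. Ribosome biogenesis genes did not differ as a list (1 higher and 1 lower of 46). In all, 2530 genes passed the threshold, 1383 higher and 1147 lower in carcinoma, and 299 and 167 of these changed at least 2-fold. The groups did not overlap in 7.90% of genes, against 0.794% by chance.

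The 8 largest rises were Terc, the RNA component of telomerase (8.45 ± 0.87 in papilloma and 12.93 ± 0.61 in carcinoma, up 4.48, SE 0.36, adjusted p = 2.52e-06, 22.4-fold), the glypican Gpc3 (up 3.56), the keratin Krt23 (up 3.41), the glycine decarboxylase Gldc (up 3.07), Renbp (up 3.03), Npnt (up 2.94), Stk32a (up 2.83) and the glutamine transporter Slc38a3 (up 2.68). The 8 largest falls were Ano3 (fell by 4.01 on the log2 scale, SE 0.12, adjusted p = 1.57e-11, 16.1-fold), Hoatz (-3.17), Sbspon (7.99-fold lower), Cdkn1a, Erc2 (-2.65), Hepacam (-2.61), Nexmif (-2.57) and Sphkap (-2.45). The naming rule required that the arrays of the groups did not overlap for any of these 16 genes. Normal arrays were at 10.34 to 10.88 for Gldc, 10.87 to 11.26 for Stk32a and 13.08 to 13.3 for Slc38a3. For these, Gpc3, Renbp and Npnt every papilloma was below every normal array. For Ano3 (6.23 to 6.61 in normal arrays), Cdkn1a, Erc2, Nexmif and Sphkap every papilloma was above. Papillomas overlapped normal arrays for the others, while every carcinoma was above for Terc and below for Hoatz, Sbspon and Hepacam. Krt23 overlapped in both tumour types. With an unpooled variance per group the calls of Gpc3, Krt23, Hoatz, Sbspon, Cdkn1a, Erc2 and Nexmif ended. Krt23 was at 6.58 to 11.49 in the carcinomas and Gpc3 at 8.36 to 12.10.

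**Figure D3:**
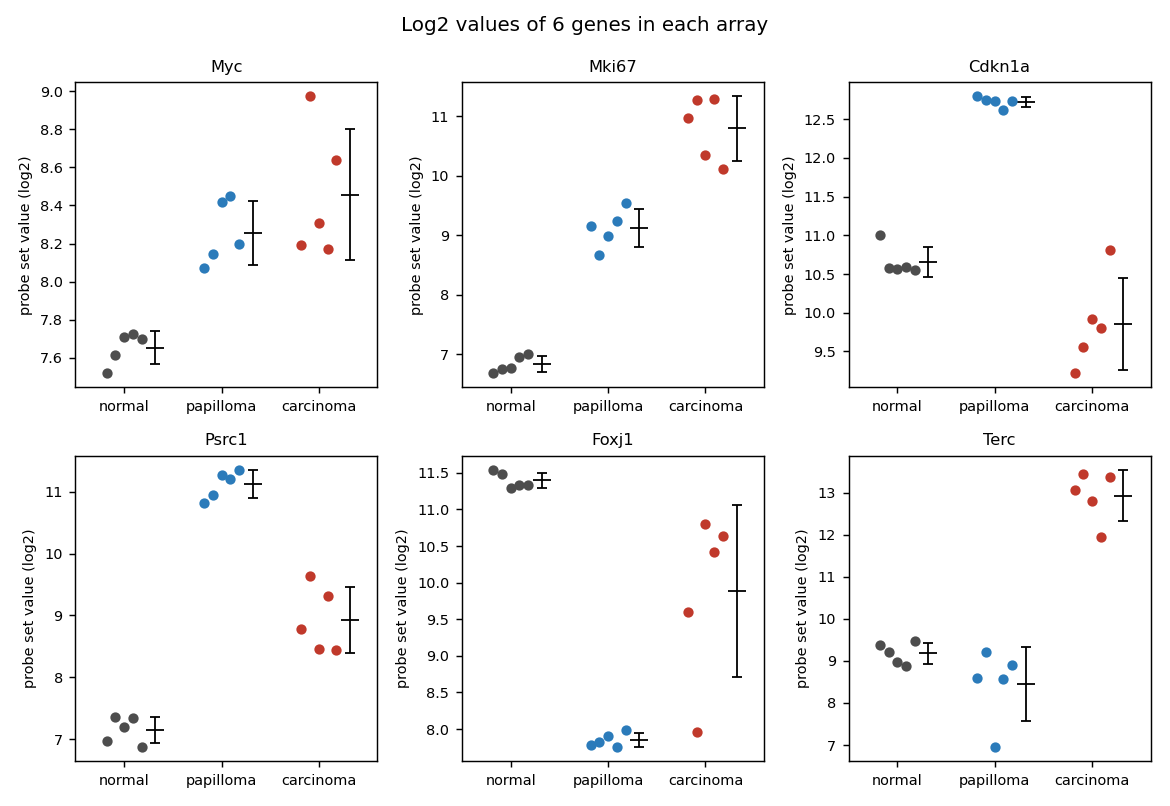
Log2 values (vertical axes) of Myc, Mki67, Cdkn1a, Psrc1, Foxj1 and Terc in each array, by group, with 1 point per array and the group mean ± SD (n = 5) beside the points; each panel has its own scale. Cdkn1a is at 12.62 to 12.80 in papilloma and 9.22 to 10.80 in carcinoma, and Terc is at 11.94 to 13.45 in carcinoma against at most 9.47 elsewhere.

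The mitotic genes had a median difference of 1.54 (38 higher and 0 lower, also when adjusted over the list alone; camera adjusted p = 1.11e-47, and 0.0549 with an estimated correlation), with Bub1, Prc1 (up 1.96) and the kinase Plk1 (up 1.86) ahead. Replication genes were higher in 27 of 39 cases and lower in 0 (32 and 0 adjusted over the list alone), with E2f8 (up 1.62), the ribonucleotide reductase subunit Rrm2 (up 1.32) and Mcm3 (up 1.26) ahead (camera adjusted p = 4.09e-24, and 0.0729 with an estimated correlation). Homologous recombination and Fanconi genes were higher in 13 of 27 cases and lower in 0 (17 and 1 adjusted over the list alone), with Fanci (up 1.15), Fancd2 (up 1.14) and Brca1 (up 1.12) ahead (camera adjusted p = 3.55e-09, and 0.109 with an estimated correlation). Replication-dependent histone genes were higher in 4 of 9 cases and lower in 0 (5 and 0 adjusted over the list alone), and this call held both ways (camera adjusted p = 2.29e-05, and 0.0189 with an estimated correlation). H2bc12 (up 1.91), H1f5 (up 1.06) and H2bc3 (up 0.83) led it, and an unpooled variance per group ended the calls of all 3 genes. The call of H1f5 also ended without papilloma arrays 2 and 4, chosen after seeing the data (0.81, adjusted p = 0.0659).

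The p53 target genes had a median difference of -0.40 (1 higher and 20 lower of 41, 3 and 26 adjusted over the list alone), and the call held both ways (camera adjusted p = 3.12e-13, and 0.00727 with an estimated correlation). Cdkn1a, Psrc1 (-2.19) and Eda2r (-2.12) were lower, and Pltp was higher (up 2.17). Among G1 regulators 9 of 17 were higher and 2 lower, also when adjusted over the list alone, with Cdkn1c (up 1.63) and Ccnd1 (up 1.52) higher (camera adjusted p = 0.00149, and 0.109 with an estimated correlation). Cdkn2a, which encodes an activator of p53 and a CDK inhibitor, was 2.82-fold higher (adjusted p = 0.0306), but the call ended without carcinoma array 1, 2 or 5 or any 1 papilloma array (1.12 to 1.53, adjusted p = 0.0514 to 0.0716). Ribosome biogenesis genes had a median difference of 0.02 (1 higher and 1 lower, also when adjusted over the list alone; camera adjusted p = 0.368), with Tcof1 up by 0.46 and Nob1 lower (-0.44), and the call of Nob1 ended without papilloma arrays 2 and 4 (-0.45, adjusted p = 0.0609).

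Multiciliated cell genes were higher in 11 of 45 cases and lower in 0 (13 and 0 adjusted over the list alone; camera adjusted p = 1.62e-05, and 0.421 with an estimated correlation). Foxj1, a transcription factor that directs motile ciliogenesis, was higher by 2.03 (SE 0.39, adjusted p = 0.00281), Pifo by 1.72 and Myb by 1.60, though Foxj1 was at 7.96 in carcinoma array 2 and at 9.60 to 10.81 in the other carcinomas, and the dimmer probe set of Myb differed by only 0.10. The calls of these 3 genes ended with an unpooled variance per group. Choroid plexus epithelial genes did not differ as a list (3 higher and 4 lower of 35, 3 and 5 adjusted over the list alone; camera adjusted p = 0.161). Ace was higher by 1.92 (SE 0.15, adjusted p = 2.29e-06), and Sulf1 (-1.22), Calml4 (-0.59) and the coagulation factor gene F5 (-0.57) were lower (adjusted p = 0.0285, 0.0238 and 0.045). Each of these 3 calls ended when single arrays were left out. For Sulf1 these were carcinoma array 1 or 5 or papilloma array 1, 2, 3 or 5 (-1.24 to -1.12, adjusted p = 0.0518 to 0.0665). For Calml4 they were carcinoma array 1 or papilloma array 3 or 5 (-0.57 to -0.55, adjusted p = 0.0551 to 0.0579). For F5 they were carcinoma array 1, 2, 3 or 5 or any 1 papilloma array (-0.62 to -0.42, adjusted p = 0.0522 to 0.101). Glycolysis and hypoxia genes were higher in 7 of 25 cases and lower in 1 (13 and 2 adjusted over the list alone), with Ndrg1 (up 2.45), Adm (up 2.20) and the angiogenic factor Vegfa (up 1.03) ahead and Pfkm lower (-0.37) (camera adjusted p = 3.27e-05, and 0.462 with an estimated correlation). The call of Adm ended without papilloma arrays 2 and 4 (1.84, adjusted p = 0.0611), and that of Pfkm with only these groups in the fit (adjusted p = 0.0764). Notch pathway genes were higher in 3 of 22 cases and lower in 0 (5 and 0 adjusted over the list alone; camera adjusted p = 0.00424, and 0.162 with an estimated correlation). These were Hey2 (up 1.97), the ligand gene Jag1 (up 1.48) and Notch3 (up 0.47), and the call of Notch3 ended without carcinoma array 2 or papilloma array 3 (0.46 and 0.36, adjusted p = 0.0529 and 0.057). For Hey2 (11.06 to 11.24 in normal arrays) and Jag1 every papilloma was below every normal array, while for Notch3 the papillomas overlapped them.

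Fibroblast, pericyte and matrix genes were higher in 10 of 28 cases and lower in 0 (12 and 0 adjusted over the list alone), and this call held both ways (camera adjusted p = 1.53e-05, and 0.0423 with an estimated correlation). Lox, which cross-links collagen, was higher by 2.19, Fn1 by 2.05 and the collagen gene Col1a2 by 1.16, and the calls of these 3 genes ended with an unpooled variance per group. For Fn1 and Col1a2 every papilloma was below every normal array, and carcinomas lay on both sides of the normal range. For Lox every carcinoma was above every normal array. Mature neuron genes passed in 0 of 20 cases, also when adjusted over the list alone, at a median difference of -0.59 (camera adjusted p = 0.00338, and 0.682 with an estimated correlation). The smallest p-values were those of Gad1 (-0.46, adjusted p = 0.0934, and 0.0315 without papilloma array 5) and Pvalb (-0.67, adjusted p = 0.137). The list's call ended without papilloma array 2 (camera adjusted p = 0.127), and the direction turned without papilloma arrays 2 and 4, the arrays high in neuron genes (0.492).

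The genes lower in carcinoma than in papilloma were unevenly spread over the chromosomes, a test chosen after seeing the data. Chromosomes 8, 12 and 19 held 394 of the 1147 lower genes (34.4%) but 11.3% of the genes tested. The odds ratios were 4.47, 3.21 and 3.32 (Fisher's exact test across genes, which are not independent replicates, adjusted p = 1.61e-48, 1.23e-19 and 3.15e-20 over all autosomes, comparisons and directions). In carcinomas the medians of single autosomes shifted. Their SD over the 19 autosomes was 0.112 ± 0.014 (SD, n = 5) against 0.024 ± 0.003 in papillomas (exact permutation test, two-sided p = 0.00794, the smallest possible). The largest shifts were -0.43 for chromosome 8 in carcinoma array 4, -0.41 for chromosome 19 in carcinoma array 5 and -0.35 for chromosome 12 in carcinoma array 3, and no papilloma value exceeded 0.06 in size. Of the 394 lower genes on these chromosomes, 200 stayed past the threshold as lower once the shifts were removed.

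**Figure D4:**
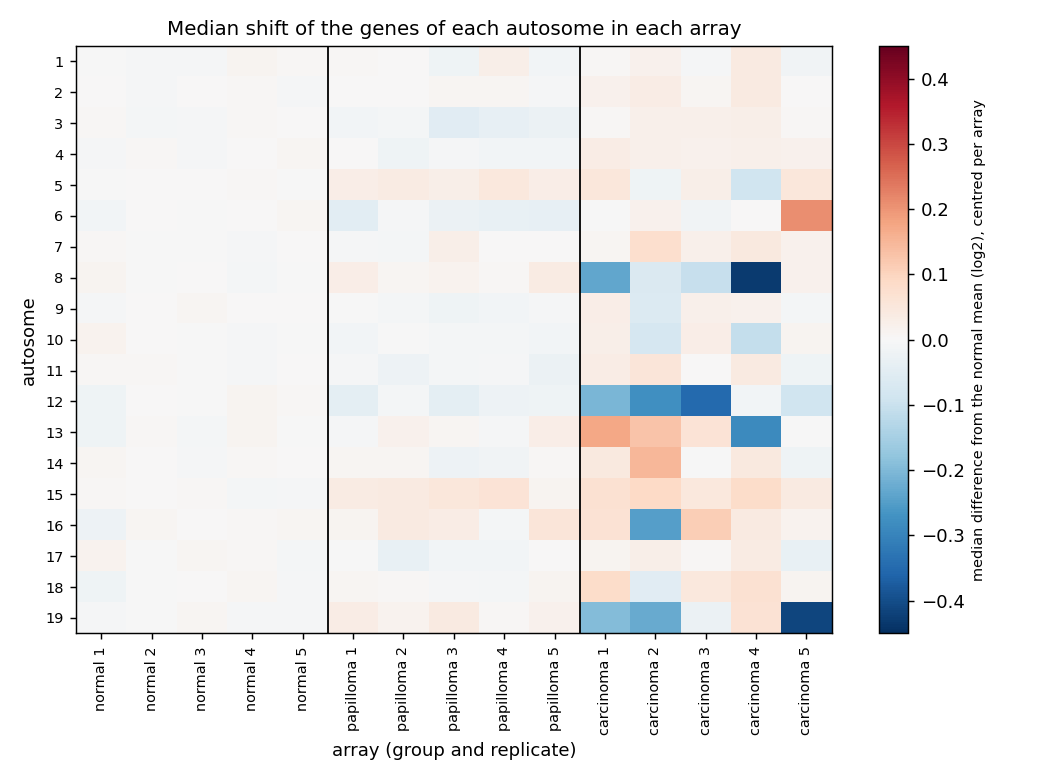
Median log2 shift (colour scale) of the genes of each of the 19 autosomes (rows) in each array (columns, grouped as normal, papilloma and carcinoma), relative to the mean of the normal arrays and centred per array. Shifts beyond 0.06 in size appear in the carcinomas alone, such as -0.43 for chromosome 8 in array 4 and -0.41 for chromosome 19 in array 5.

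The count for carcinoma against papilloma depended on the estimate of the spread. It was 1329 genes with only these groups in the fit and 135 with each gene's own unpooled variance per group. The latter ended the calls of 40 of the 55 genes named here beside Myc and Atoh1, among them Plk1, E2f8, Rrm2, Mcm3, Fanci, Fancd2, Brca1, Eda2r, Pltp, Ccnd1, Ndrg1, Adm, Vegfa, Hey2 and Jag1. The calls that held were those of Terc, Gldc, Renbp, Npnt, Stk32a, Slc38a3, Ano3, Hepacam, Sphkap, Ace, Prc1, Psrc1 and Cdkn1c, and Gad1 and Pvalb had not passed. The fit on only these groups also ended the calls of Sulf1, Calml4, F5, Nob1, Notch3 and Cdkn2a. Against normal tissue an unpooled variance ended the calls of 5 named genes in carcinoma (Car2, Mthfd1, Pfkm, Ermn and Cspg4) and 1 in papilloma (Nefl).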

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

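The tests of the patterns weighed here were chosen after the results were seen, and the splits of the arrays were planned before. Chance is argued against as the source of the gene counts, to the limit of 1 in 100 splits. With only the 2 compared groups in the fit, carcinoma against normal gave 8144 genes, papilloma against normal 8578 and carcinoma against papilloma 1329. Among 100 of the 126 splits of each 10 arrays, the real split included, only 1 split, the real one, reached that count in each comparison. The highest count among the other splits was 1, 2 and 2. Every other split mixes the groups, which adds their difference to the spread and lowers its count. The splits cannot tell the tumour type from another difference that follows the groups.

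In the carcinomas, 31 of 95 array and chromosome medians were beyond 0.06, the largest papilloma value (17 lower, 14 higher). With each chromosome cut into 3 parts of near-equal gene number, 14 of the 31 had every part beyond 0.06. The others did not all span the chromosome. The middle part of chromosome 16 in carcinoma array 1 went the other way (-0.012, against a median of 0.065). So did the last part of chromosome 8 in carcinoma array 2 (0.004, against -0.064). A normalization error that depends on expression level is argued against for the 14 values with all 3 parts beyond 0.06. For each of them a permutation test over random gene sets matched on expression level gave p = 1e-04, the smallest that 10000 sets can give. The same test argues against it for 10 of the other 17 values (permutation p of at most 6e-04), and for the remaining 7 (permutation p = 0.003 to 0.03) it stays open. Gain or loss of chromosome copies in single tumours may underlie the shifts in these 14. DNA was not analysed here, and the floxed p53 genotype, which differs between the tumour types, stays open as untested.

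Normal arrays 2 to 5 had both Xist and Y-linked transcripts. Probe sets that give signal without their transcript are argued against, since 0 of the 10 tumour arrays had both. Tumour tissue of the other sex was weighed with 14 genes chosen as far higher in both tumour types than in these same normal arrays. They gave apparent tumour shares of -0.008 to -0.004, against shares of the rarer sex of 0.16 to 0.61. The choice favours low shares. The test therefore argues only against tumour tissue that holds these 14 genes at the papilloma level. Tissue of male and female mice pooled per sample is a candidate explanation. The Y-linked and Xist shares summed to 1.11 to 1.23, within the 0.65 to 1.27 of the tumour arrays. That range is wide, so the sums cannot decide for or against pooling. No biological explanation was tested. If normal samples were pooled, the SD of the normal arrays would not be the spread between single mice. That SD enters the variance shared by all comparisons.

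Of the multiciliated cell genes, 11 were higher in carcinoma than in papilloma, and residual normal choroid plexus in the carcinomas was weighed as a source. For each gene the difference of carcinoma from papilloma was taken as a share of the difference of normal from papilloma, in linear values. This assumes that the papillomas hold no normal tissue. Across 66 genes lost in papilloma and outside the multiciliated list the median share was 0.038 (bootstrap interval 0.02 to 0.085). This set was not cleared of all cilia genes and held the cilia gene Drc7, so it is not independent of the pattern weighed. Of the 66, 56 were below 0.226, the share Pifo would need, while 10 were not. Foxj1, Enkur, Tekt2 and Ccdc40 were above the level that a share of 0.085 gives. Their lower 95% bounds were 0.09 or more on the log2 scale. That share bounds a median, and single genes spread more widely. The 95% bounds also rest on a spread pooled over the groups. The test therefore cannot decide for these 4 genes. Deup1, Myb, Gmnc and Mcidas were past the threshold as higher than normal (4 of 4), which argues against this source for them. For Pifo, Spag6l and Cfap52, whose lower 95% bounds were at most -0.02, residual tissue and a change of these genes in the tumours cannot be told apart. The floxed p53 genotype stays open as untested.

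Of 399 groups of 5 arrays, for 133 genes, 27 held an array far from the other 4, where chance gives about 1 in 20. They were 15 papilloma, 8 normal and 4 carcinoma groups. Papilloma array 1 was high in Ndrg1 (11.36 against 9.25 to 9.67), Ccn1 (11.41 against 8.92 to 9.42) and Atf3 (11.39 against 7.94 to 8.65). It was low in Mthfd1 (11.23 against 11.38 to 11.43), Slc38a3 (9.28 against 9.85 to 10.05) and Tcof1 (8.49 against 8.87 to 9.02). Papilloma array 2 was low in Fanci (6.76 against 6.95 to 7.02), Rad54l (6.47 against 6.88 to 7.03) and Prc1 (7.87 against 8.31 to 8.38). Papilloma array 3 was high in Dynlrb2 (6.83 against 6.57 to 6.64) and Slc47a1 (7.44 against at most 7.05). The same array was low in Terc (6.95 against 8.57 to 9.22) and Notch3 (7.42 against 7.91 to 8.03). Papilloma array 4 was high in St8sia6 (11.94 against 10.43 to 10.68) and papilloma array 5 in Pbk (8.94 against 8.43 to 8.58). Carcinoma array 2 was low in Car2 (9.68 against 12.19 to 12.57) and high in Fancd2 (9.09 against 7.95 to 8.26). Carcinoma array 3 was high in Dynlrb2 (7.32 against 6.56 to 6.66) and carcinoma array 4 low in Rdh5 (10.08 against 11.29 to 11.60). Normal array 1 was high in Cdkn1a (11.01 against 10.56 to 10.59), Bmp5 (8.46 against at least 7.87) and Dkk3 (9.42 against 9.07 to 9.10). Normal array 3 was low in Espl1 (7.44 against 7.62 to 7.70) and normal array 5 in Pfkm (11.70 against 11.80 to 11.81). Normal array 4 was high in Ak7 (11.26 against 10.88 to 10.94) and Cfap52 (12.34 against 12.09 to 12.15) and low in Tcof1 (8.06 against 8.27 to 8.32).

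A signal also appeared in data outside the comparisons. Of 17634 probe sets without a single gene name, 3183 passed the threshold for carcinoma against normal (1610 higher, 1573 lower), 2970 for papilloma against normal (1419 and 1551) and 465 for carcinoma against papilloma (259 and 206).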

How the results depend on the processing

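Of the values of the named genes other than Myc and Atoh1 under the alternatives, 1498 of 1517 kept their direction and side of the threshold for carcinoma against normal, 1201 of 1215 for papilloma against normal and 1230 of 1316 for carcinoma against papilloma. The cause was not tested unless stated. For carcinoma minus papilloma, genes past the threshold numbered 1329 with only the 2 groups in the fit, 135 with an unpooled variance per group (57 also changed at least 2-fold; 40 of 55 named genes lost) and 1587 without papilloma arrays 2 and 4 (fewer arrays; chosen after seeing the data). Without these arrays the mature neurons list turned upward (adjusted p = 0.492). Lists past the threshold numbered 2, 4 and 3 in the order of the report with an estimated correlation, 10 for papilloma minus normal with a filter on dim genes (fewer genes tested) and 8 for carcinoma minus papilloma by fry. Shared changes of at least 2-fold numbered 558 higher and 680 lower, and 1868 genes were lower in both with split controls (fewer arrays). Atoh1 in carcinoma minus normal turned to 0.009 under quantile normalization and 0.006 at a common median, and ranged from -0.088 to 0.034 with 1 array left out, turning without normal array 4 or carcinoma array 1 or 3. With 1 array left out, genes past the threshold ranged from 7703 to 8745, 6703 to 7108 and 1882 to 3038 in the same order, and those changed at least 2-fold from 1841 to 2054, 1614 to 1713 and 442 to 510. A replicate block gave 8220, 7180 and 2268 genes and ended the call of Sulf1 in carcinoma minus papilloma (adjusted p = 0.0555). The alternatives chosen after seeing the data also included chromosome-centred carcinoma arrays, genes on X and Y left out and 1 weight per group. Signal close to background limits what dim probe sets such as Atoh1 can show.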

Other observations

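Gene groups that the comparisons above leave out were tested in the same way. In papilloma against normal, DNA replication genes rose in 29 of 39 cases and fell in 1 (31 and 2 adjusted over the list alone; camera adjusted p = 1.76e-10, and 0.329 with an estimated correlation). Homologous recombination and Fanconi genes rose in 16 of 27 and fell in 2 (18 and 2 adjusted over the list alone; 0.000914, and 0.362 with an estimated correlation). Endothelial genes rose in 12 of 21 and fell in 1 (13 and 1 adjusted over the list alone; 0.00268, and 0.481 with an estimated correlation). Glycolysis and hypoxia genes rose in 11 of 25 and fell in 1 (12 and 2 adjusted over the list alone; 0.0194, and 0.716 with an estimated correlation). Immediate early genes rose in 6 of 19 and fell in 0, also over the list alone (0.031, and 0.716 with an estimated correlation). The calls of the last 2 lists ended without papilloma array 1 (0.0868 and 0.0957). Oligodendrocyte lineage genes fell in 6 of 15 and rose in 1, also over the list alone (0.0131, and 0.481 with an estimated correlation). Granulocyte and mast cell genes fell in 5 of 17 and rose in 0, also over the list alone (0.031, and 0.362 with an estimated correlation). Replication-dependent histone genes rose in 3 of 9 and fell in 1, also over the list alone (0.107).

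In carcinoma against normal, replication-dependent histone genes rose in 7 of 9 cases and fell in 1, also over the list alone (camera adjusted p = 0.00159, and 0.0757 with an estimated correlation). Notch pathway genes rose in 12 of 22 and fell in 4, also over the list alone (0.0465, and 0.331 with an estimated correlation). This call ended without normal array 2, 4 or 5 or carcinoma array 4 or 5 (0.0534 to 0.0762). Hindbrain Hox genes fell in 6 of 14 and rose in 0, also over the list alone (0.0369, and 0.398 with an estimated correlation), and the call ended without carcinoma array 2 or 3 (0.0707 and 0.0553). Proneural genes fell in 3 of 20 and rose in 0, also over the list alone (0.0369, and 0.623 with an estimated correlation), and the call ended without normal array 1 or carcinoma array 3 or 5 (0.0528 to 0.071). Granulocyte and mast cell genes fell in 5 of 17 and rose in 0, also over the list alone (0.0369, and 0.354 with an estimated correlation), and the call ended without normal array 1 or carcinoma array 1 or 2 (0.0515 to 0.0557).

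In carcinoma against papilloma, proneural genes were lower in 2 of 20 cases and higher in 0, also over the list alone (camera adjusted p = 0.000481, and 0.462 with an estimated correlation). That call ended without papilloma arrays 2 and 4, chosen after seeing the data (0.522). Endothelial genes were higher in 1 of 21 and lower in 0 (0 and 0 adjusted over the list alone; 0.00481, and 0.518 with an estimated correlation), which ended without carcinoma array 1 (0.0527). Macrophage and microglia genes were higher in 2 of 26 and lower in 0, also over the list alone (0.0197, and 0.682 with an estimated correlation), which ended without carcinoma array 2 or 4 (0.166 and 0.44). Oxidative phosphorylation genes were lower in 3 of 28 and higher in 0, also over the list alone (0.0304, and 0.742 with an estimated correlation), which ended without carcinoma array 2 or 4 or papilloma array 1, 2 or 5 (0.0552 to 0.609). Neural progenitor genes were higher in 4 of 24 and lower in 0 (5 and 0 adjusted over the list alone; 0.0441, and 0.462 with an estimated correlation). This ended without carcinoma array 1 or 2 or papilloma array 1, 3 or 5 (0.0527 to 0.136). Nucleotide and polyamine genes were higher in 4 of 22 and lower in 2 (5 and 2 adjusted over the list alone; 0.0932), meningeal genes in 1 and 1 of 15 (2 and 1; 0.573), immediate early genes in 2 and 0 of 19 (1 and 0; 0.172) and oligodendrocyte genes in 0 and 0 of 15 (0 and 0; 0.419).

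The remaining lists did not pass by camera. Adjusted p-values are given in the order carcinoma against normal, papilloma against normal and carcinoma against papilloma, with genes higher and lower in brackets. They were 0.95, 0.755 and 0.856 for the Hedgehog pathway (3 and 6, 3 and 4, 3 and 0 of 17) and 0.361, 0.179 and 0.372 for growth factors and receptors (6 and 12, 8 and 12, 6 and 3 of 33). Forebrain choroid plexus regional genes had 0.994, 0.67 and 0.54 (1 and 1, 0 and 1, 1 and 0 of 10) and astrocyte genes 0.0695, 0.309 and 0.162 (2 and 6, 2 and 2, 1 and 2 of 16). Lymphocyte genes had 0.585, 0.825 and 0.402 (1 and 4, 0 and 1, 0 and 1 of 20). Antigen presentation and interferon genes had 0.70, 0.107 and 0.341 (4 and 6, 4 and 10, 2 and 2 of 28). The mean of that list was 8.95 in carcinoma array 4 and 7.82 to 7.94 in the other carcinomas, and without carcinoma array 4 it passed as lower than normal (0.0496). That array also stood apart on the third principal component (46.41 against at most 8.68). Apoptosis genes had 0.95, 0.611 and 0.176 (6 and 7, 6 and 8, 2 and 0 of 20). Adjusted over the list alone, the counts were 4 and 6, 3 and 4, 3 and 1 for Hedgehog, 8 and 12, 8 and 13, 8 and 4 for growth factors, and 1 and 1, 0 and 0, 1 and 1 for forebrain genes. Astrocyte counts stayed as they were, lymphocyte counts were 1 and 3, 0 and 0, 0 and 1, antigen presentation counts 4 and 6, 4 and 10, 4 and 2, and apoptosis counts 6 and 8, 7 and 9, 2 and 0.

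Other lists passed in some comparisons and not in others, by the same test. Carcinoma and papilloma against normal gave 0.70 and 0.107 for oxidative phosphorylation (2 and 3, 8 and 2 of 28), 0.85 and 0.309 for neural progenitor genes (4 and 1, 2 and 5 of 24) and 0.796 and 0.309 for macrophages (2 and 2, 1 and 3 of 26). Adjusted over the list alone, only the progenitor count against carcinoma changed, to 4 and 0. Papilloma against normal gave 0.755 for the Notch pathway (7 and 5 of 22, 8 and 5 over the list alone), 0.238 for Hox genes (2 and 2 of 14) and 0.909 for proneural genes (0 and 1 of 20). Carcinoma against papilloma gave 0.657 for the Wnt and BMP pathway (3 and 1 of 29), 0.0744 for Hox genes (0 and 1 of 14) and 0.733 for granulocytes (0 and 0 of 17). Carcinoma against normal gave 0.145 for the Wnt and BMP pathway (5 and 10 of 29) and 0.70 for fibroblast genes (9 and 9 of 28, 11 and 9 over the list alone). Median, mean and test differed in sign for 11 results, none of which passed. An example is the Notch pathway in papilloma against normal, with a median of 0.05, a mean of -0.10 and an upward test.

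Gh and Prl, pituitary hormone genes chosen after their values were seen, were measured per array. Gh was at 9.66 to 10.36 in the normal arrays and at 6.52 to 8.17 in the tumour arrays. Prl was at 6.48, 7.48, 10.75, 8.03 and 11.57 in normal arrays 1 to 5, at 7.74 in papilloma array 3 and at 5.32 to 5.79 in the other tumour arrays.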
